A study of Mus musculus with 9 samples.

How the data were processed

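Total RNA of mouse hearts was extracted with Trizol and made into libraries with a directional (strand-keeping) NEBNext kit, per the labels' protocols. The deposited table holds raw counts per gene symbol for 9 libraries, whole numbers that the authors did not normalize as far as the values show. Per the submitters' processing notes the tools included Trim Galore 0.6.10, HISAT2 2.2.1, SAMtools 1.15, StringTie 2.2.1 and DESeq2 1.42.0, with the builds GRCm38 and mm10. Which tool made the counts, the annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here. Libraries were matched to groups through the labels, and all 9 sample columns were used. The labels number the hearts of a group without saying that each came from its own mouse, so p-values measure the spread between these samples.

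The table has 55401 rows and 55291 distinct symbols, and 110 rows repeat a symbol of another row. Such rows were kept apart, and the row with the largest total carries the plain symbol. Total counts per library were 59702513 to 109162107. Mitochondrially encoded genes took 23.78% to 38.45% of the counts, and gene models on chromosome 1 between 24611535 and 24616197, nuclear copies of mitochondrial DNA, took 7.395% to 10.47%, so some reads from mitochondrial transcripts were counted at the copies. Values of pseudogenes, near-identical paralogs and overlapping or antisense genes are uncertain for the same reason. The 9 libraries were each checked for Y-linked transcripts and low Xist, and 9 of 9 matched male mice. No pair of libraries in a group agreed within sampling noise (chi-square per degree of freedom of 23.53 or more). Gene positions and identifiers are from GENCODE's annotation of GRCm38, in which 18622 of the 19051 tested symbols (97.7%) were found.

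The main test was edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), two-sided, with TMM factors, filterByExpr with a minimum count of 10, and Benjamini-Hochberg adjusted p under 0.05 over the 19051 genes kept. All 9 libraries entered 1 fit with the group as the only term, so the 3 groups share 1 estimate of the spread. The biological coefficient of variation was 42.1% and the prior degrees of freedom 3.53. Log2 values for plots and principal components used a prior count of 2. Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, two-sided and adjusted over 31 lists with at least 3 measured members, again with an estimated correlation, and with fry, which tests whether a list's genes move on balance 1 way. Older symbols in the lists were matched to those in the table (Ctgf to Ccn2, for example). An exact permutation test of 3 against 3 hearts cannot go below 0.1 and was not used.

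The lists, groups, main test and most alternatives were set before the data were examined. The lists covered the heart muscle programs (hypertrophic fetal program, contraction and calcium, atrial markers), matrix (fibrillar and matricellular, basement membrane, TGF-beta and activin signalling), metabolism (fatty acid oxidation, nuclear and mitochondrial oxidative phosphorylation, branched-chain amino acids and ketones, glycolysis), growth (Myc targets, ribosomal proteins, proliferation), stress (immediate early genes, integrated stress and unfolded protein response, p53, interferon), the circadian clock, chemokines and cytokines, and markers of resting fibroblasts, neutrophils, macrophages, lymphocytes, endothelium, smooth muscle and pericytes, epicardium, adipocytes, Schwann cells, erythroid cells, and lung and skeletal muscle. Named genes were Myc, Tcf21, Postn, Cxcl1, Cxcr2, Nppa, Nppb, Myh7 and Col1a1 in every comparison. They also were up to 10 genes each way that passed, or where fewer than 5 did, the genes of smallest p up to 5 each way. These had at least 1 CPM, no predicted model and no overlap of the CPM of the 2 groups, so their separation was fixed by the rule. Also named were up to 4 members of a list that passed or else its members with the highest CPM. The last were genes that passed both TAC comparisons with opposite signs. Genes named because they passed over their list alone, by DESeq2 or without a library, Hspa1a, Tnnt2 and the chromosome 15 genes Psca, Arc and Lypd2 outside the rule were chosen after their values were seen. Of the genes that the rule for named genes selects, 1 is not reported here.

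The alternatives were RLE and upper-quartile factors, library size alone, DESeq2 1.42.0, limma-voom with quality weights, no low-count filter, a filter of at least 1 CPM in 3 libraries, a fit to only the 2 groups compared, the replicate number as a block, removal of mitochondrial genes, a fold threshold of 1.2, and each library left out in turn. Chosen after seeing the data were a robust quasi-likelihood fit, limma-voom without weights, rows of the same symbol summed, removal of mitochondrial genes with their nuclear copies (models within 10 kb), DESeq2 without TAC replicate 2 or 3, and the endothelial minus cardiomyocyte level of each library (mean log2 CPM of the endothelial list minus that of the contraction and calcium list) as a covariate.

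The tests were checked on simulated counts drawn for the 19051 genes from their means, dispersions and library sizes, with 200 genes changed. For TAC against control edgeR recovered 7% of the genes changed 2-fold and 65% of those changed 4-fold with 2 false calls, and DESeq2 33% and 90% with 49 false calls. For KO-TAC against TAC edgeR recovered 4% and 68% with 3 false calls and DESeq2 29% and 94% with 69. For KO-TAC against control edgeR recovered 5% and 70% with 5 and DESeq2 26% and 92% with 62. In these simulations the false calls of DESeq2 exceeded the share that an adjusted p under 0.05 allows. Its counts and adjusted p below carry that limit. Camera called 3 of 3 lists of 10 genes shifted 2-fold and 0 of 20 unchanged lists in each comparison. The simulated genes were independent, so this says nothing of lists whose members vary together. All groups also had 1 shared dispersion per gene in the simulation. The TAC hearts in fact spread more (median SD of log2 CPM 0.604, against 0.171 in control and 0.33 in KO-TAC hearts). The simulated rates may therefore not hold for these data.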

Results

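Gene expression was measured by RNA sequencing of total heart RNA from mice in 3 groups of 3 libraries each. Control hearts were from wild-type mice and are the sham-operated group of the design. TAC hearts were from wild-type mice after transverse aortic constriction, a surgical narrowing of the aorta that loads the left ventricle, and carry a 12-week time in their titles. KO-TAC hearts, also titled 12 weeks, were from mice in which Myc was floxed and deleted in fibroblasts by a tamoxifen-inducible Cre under Tcf21, a gene expressed in cardiac fibroblasts. Male mice aged 8 to 12 weeks underwent the operations. Tamoxifen, which activates this Cre, is described for the knockout line at 45 mg/kg for 5 days, and whether wild-type mice received it is not given in the sources used here. No knockout group without TAC and no Cre control group was analysed here, so tamoxifen and Cre cannot be separated from Myc deletion in the comparisons with KO-TAC. The total count per library ranged from 59702513 (TAC replicate 3) to 109162107 (KO-TAC replicate 1). From 21510 to 25001 genes had a count in a library. Expression values are CPM (counts scaled to a common library total, with TMM factors), as mean ± SD over the 3 hearts of a group (n = 3), and fold changes come from the edgeR fit to all 9 libraries.

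The 3 TAC hearts differed from one another far more than the hearts of the other groups. Atp2a2, the sarcoplasmic reticulum calcium pump, was counted at 449 CPM in the lowest TAC heart and 12200 CPM in the highest, against 12400 to 13400 CPM in control hearts. The median SD of log2 CPM across genes was 0.171 in control, 0.604 in TAC and 0.33 in KO-TAC hearts. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.971 to 0.976 between control hearts, 0.957 to 0.965 between KO-TAC hearts and 0.879 to 0.943 between TAC hearts. On the first principal component, which held 45.5% of the variance, TAC replicate 3 scored 168.4, TAC replicate 1 scored 55.7 and TAC replicate 2 scored -38.2, near the control hearts at -59.6 to -53.

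**Figure D1:**
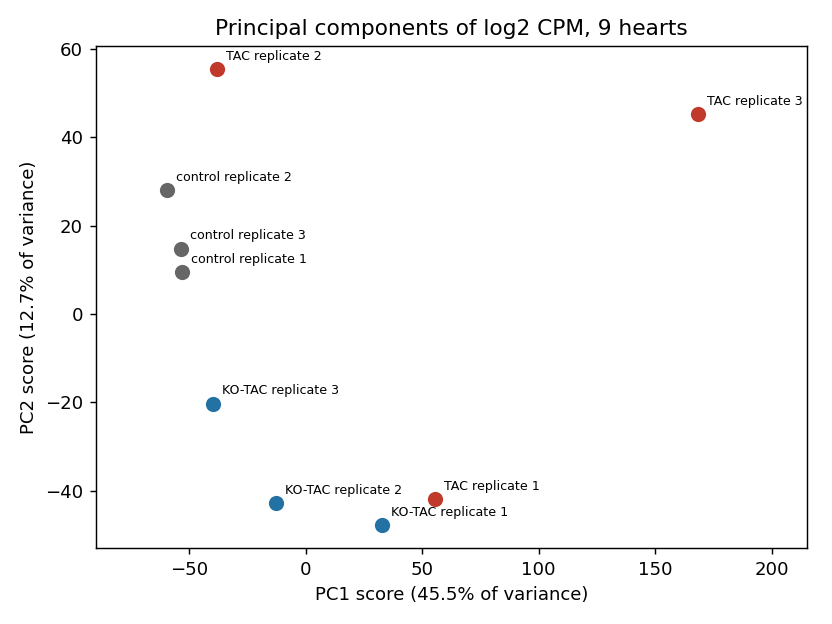
Principal component scores of log2 CPM for the 9 hearts, with PC1 (45.5% of the variance) on the x axis, PC2 (12.7%) on the y axis and 1 point per heart coloured by group. The 3 control hearts lie between -59.6 and -53 on PC1, while the TAC hearts spread from -38.2 to 168.4.

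Myc, the targeted transcription factor gene (chromosome 15, 61985391 to 61990374, GRCm38), was measured at 2.06 ± 0.46 CPM in control, 9.79 ± 4.1 CPM in TAC and 3.61 ± 1.5 CPM in KO-TAC hearts. All 3 KO-TAC hearts (1.87 to 4.75 CPM) lay below all 3 TAC hearts (6.22 to 14.2 CPM), in the direction of the labels. Over all genes 9.96% separated in this way, up or down, between KO-TAC and TAC, beside 10% by chance. Separation alone is therefore no evidence of a difference here. The log2 difference of KO-TAC from TAC was -1.44 (SE 0.41), 2.71-fold lower, and did not pass after adjustment over all genes (edgeR adjusted p = 0.56, DESeq2 0.082). It passed under limma-voom with quality weights (-1.74, adjusted p = 0.031). In TAC against control the log2 difference was 2.25 (SE 0.42; edgeR adjusted p = 0.13, DESeq2 adjusted p = 0.0001), and in KO-TAC against control 0.82 (SE 0.41, edgeR adjusted p = 0.85) with overlapping ranges. The RNA is of the heart, so Myc transcripts of cells without Cre were counted too. The list of immediate early genes, which does not include Myc, followed the same pattern. All 24 members were higher in TAC than in control and lower in KO-TAC than in TAC. A lower Myc level in KO-TAC hearts therefore does not by itself show the deletion. Tcf21 itself was at 5.91 ± 0.87 CPM in control, 6.31 ± 0.5 CPM in TAC and 4.04 ± 0.13 CPM in KO-TAC hearts; the KO-TAC value, 1.56-fold below TAC, did not pass (edgeR adjusted p = 0.63).

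**Figure D2:**
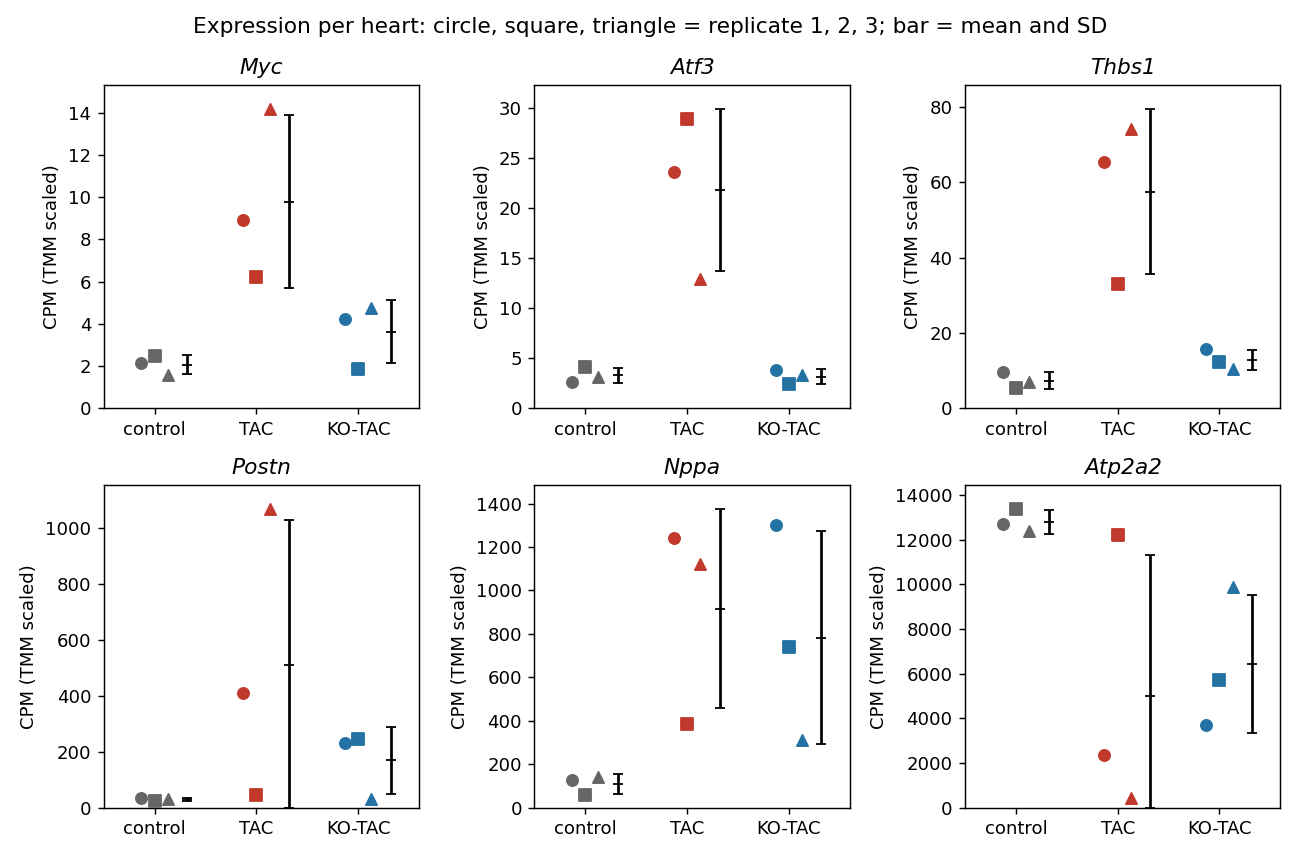
CPM of 6 genes in each heart (y axis from 0, linear) by group (x axis), with circles, squares and triangles for replicates 1, 2 and 3 and black bars for the mean and SD, drawn down to 0 where the SD exceeds the mean. Myc, Atf3 and Thbs1 are higher in all 3 TAC hearts than in any control or KO-TAC heart, Nppa is higher in all TAC and KO-TAC hearts than in any control heart, and Postn and Atp2a2 vary widely among TAC hearts.

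Comparison of TAC with control asked which genes pressure overload moved in wild-type hearts. Extracellular matrix genes rose as a list, with a median fold of 5.13 and all 34 measured members higher (adjusted p = 0.47 with an estimated correlation). Immediate early genes, transcription factors and regulators induced within minutes by growth and stress signals, rose as a list by a median fold of 2.67, with all 24 members higher (adjusted p = 0.14 with an estimated correlation). The hypertrophic fetal program rose with a median fold of 2.21 (14 of 17 members higher), endothelial markers with 1.78 and genes of TGF-beta and activin signalling with 1.92. Their adjusted p with an estimated correlation was 0.17, 0.47 and 0.47. Fatty acid oxidation genes (31 of 32 lower), adult cardiomyocyte contraction and calcium genes (22 of 22 lower) and branched-chain amino acid and ketone catabolism genes (20 of 20 lower) fell as lists, by medians of -1.07, -0.87 and -0.96 on the log2 scale. Each had adjusted p = 0.58 with an estimated correlation.

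Among matrix genes, Thbs1, a secreted activator of TGF-beta, was measured at 57.6 ± 22 CPM in TAC against 7.24 ± 2.2 CPM in control hearts, and Ccn2, a matricellular growth factor, at 291 ± 83 against 49.9 ± 7.5 CPM. Thbs4 was 38.8-fold, Timp1 24.4-fold and Col12a1 20.9-fold higher. Postn, a marker of activated fibroblasts, was at 510 ± 520 CPM against 30.1 ± 5.5 CPM, and its TAC values ran from 45.8 to 1070 CPM. Without TAC replicate 3 the fold of Thbs4 was 20.3, that of Timp1 7.15 and that of Postn 7.47 (16.9 with it). Col1a1, the main fibrillar collagen chain, was 2.40-fold higher with overlapping ranges. Adjusted over the list alone, 28 of the 34 matrix genes passed and 6 did not, while 0 passed over all genes (camera adjusted p = 4e-19 for the list). In TGF-beta and activin signalling, Ltbp2 was 39.8-fold higher, and 16.7-fold without TAC replicate 3. Adjusted over the list alone 14 members passed as higher and 1 as lower (camera adjusted p = 4.7e-08), with 4 higher without control replicate 2, 7 and 9 without control replicates 1 and 3, and 10 without TAC replicate 3 or KO-TAC replicate 2.

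Of the immediate early genes, 21 of 24 passed when adjusted over the list alone. Atf3, a stress-induced transcription factor, was at 21.8 ± 8.1 CPM in TAC against 3.25 ± 0.76 CPM in control hearts. Egr3 was 9.55-fold and Nr4a3 8.96-fold higher (5.14-fold without TAC replicate 2). Each of these 3 genes was higher in all 3 TAC hearts than in any control heart. Over all genes 28.1% separated, up or down, in this comparison, beside 10% by chance. The list was called by camera (adjusted p = 2.5e-19) and by fry (adjusted p = 0.019). In the hypertrophic fetal program, Nppa, which encodes atrial natriuretic peptide, was at 917 ± 460 against 109 ± 44 CPM. Nppb was 3.77-fold, Acta1 8.92-fold (4.85-fold without TAC replicate 1) and Myh7, the slow myosin heavy chain, 2.21-fold higher. Adjusted over the list alone 7 of 17 members passed (camera adjusted p = 1.4e-06, fry adjusted p = 0.025).

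Endothelial markers included Aqp1 at 601 ± 230 against 223 ± 31 CPM and Rgcc, 3.11-fold higher. Of the 20 markers 11 passed when adjusted over the list alone (camera adjusted p = 4e-08), with 1 without control replicate 1, 2 or 3, 7 without TAC replicate 1 and 18 without TAC replicate 2. Cytosolic ribosomal protein genes were higher in 49 of 50 cases with a median fold of 1.54. Over the list alone 0 passed (camera adjusted p = 3.1e-11, adjusted p = 0.58 with an estimated correlation). These mRNAs are short, and the Spearman correlation across genes of transcript length with the log2 difference from the control mean was -0.18, -0.17 and -0.02 in TAC replicates 1, 2 and 3 and -0.23 to -0.16 in KO-TAC hearts, against -0.07 to 0.08 in control hearts. The ribosomal list mean was 0.77, 0.3 and 0.75 above control in TAC replicates 1, 2 and 3 on the log2 scale. In KO-TAC replicates 1, 2 and 3 it was 0.75, 0.47 and 0.17. The list level thus did not follow the length correlation from heart to heart. Chemokines and cytokines (median fold 2, camera adjusted p = 0.0015), macrophage and monocyte markers (1.49, 0.0035), proliferation genes (2.15, 0.0041), epicardial and mesothelial markers (2.03, 0.002), resting fibroblast markers (1.46, 0.015), the integrated stress and unfolded protein response (1.33, 0.011) and the p53 response (1.28, 0.037) were also called as higher, with adjusted p of 0.47 to 0.67 with an estimated correlation. Cdkn1a, the cell cycle inhibitor p21, was 5.72-fold and Atf4 1.90-fold higher. Cxcl1, a neutrophil-attracting chemokine, was at 3.09 ± 1.3 against 0.729 ± 0.29 CPM, and Cxcr2, the gene of its receptor, was at 0.0702 ± 0.061 against 0.151 ± 0.15 CPM, too low for a difference to be detectable at this depth.

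In the lists that fell, single genes rarely passed. Atp2a2 was at 5020 ± 6300 against 12800 ± 560 CPM, and Myh6, the fast myosin heavy chain of adult mouse heart, at 17500 ± 14000 against 33500 ± 150 CPM. Lpl was at 3010 ± 2500 against 5930 ± 130 CPM and Fabp3 at 1400 ± 1200 against 2190 ± 120 CPM. Without TAC replicate 2 these 4 genes were 9.12-fold, 3.52-fold, 3.62-fold and 2.57-fold lower, against 2.56-fold, 1.91-fold, 1.97-fold and 1.56-fold with it. Gja1, the gap junction gene of ventricular muscle, was 2.80-fold lower and was the only one of the 22 contraction and calcium genes to pass over the list alone (adjusted p = 0.047). None passed without control replicate 1, 2 or 3, TAC replicate 1 or 3 or KO-TAC replicate 2, and 15 passed without TAC replicate 2. Camera gave adjusted p = 1.3e-08 for fatty acid oxidation, 1.6e-06 for contraction and calcium and 3.4e-06 for branched-chain amino acid and ketone catabolism. Nuclear oxidative phosphorylation subunits were lower in 47 of 53 cases with a median of -0.35 (camera adjusted p = 0.00054, adjusted p = 0.77 with an estimated correlation), and without TAC replicate 3 their median was 0.10 and the call was lost (adjusted p = 0.31). These lists moved together with cell-type markers in the same hearts: relative to control, the median of contraction and calcium genes was -1.4, -0.04 and -2.45 in TAC replicates 1, 2 and 3, that of endothelial markers 0.8, 0.14 and 1.36, and that of matrix genes 2.15, 0.39 and 2.96. A fit with the endothelial minus cardiomyocyte level of each heart as a covariate was added after seeing the data. That level was -1.03 to -0.87 in control, -0.67 to 2.91 in TAC and -0.64 to 0.35 in KO-TAC hearts. The level differs between the groups and includes contraction genes, which can change within cardiomyocytes, so it is not a measure of cell shares alone. With it the matrix median was 0.29 in place of 2.36 (camera adjusted p = 0.028). Fatty acid oxidation (0.48), nuclear oxidative phosphorylation (0.73) and branched-chain amino acid genes (0.41) were then called as higher, and macrophage (-0.23) and proliferation genes (-0.49) as lower. The hypertrophic fetal program (1.11) and immediate early genes (0.70, a fold of 1.63 in place of 2.67) were still called as higher, as were TGF-beta and activin genes (a fold of 1.17 in place of 1.92) and epicardial markers (3.21 in place of 2.03), and the calls of resting fibroblast, chemokine and p53 genes were lost (adjusted p = 0.23 to 0.38). None of the calls with the covariate held with an estimated correlation (lowest adjusted p = 0.18).

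Over all genes, 0 of 19051 passed the edgeR quasi-likelihood test at an adjusted p under 0.05 in TAC against control (lowest adjusted p = 0.083), while 4054 had an unadjusted p under 0.05 against 953 by chance, 2514 of them higher. The genes of smallest p were picked among those whose 2 groups did not overlap, and are given as values that did not pass. On the higher side they were Thbs1, Atf3, Ccn2, Tppp3 (2.85-fold) and Ddit4 (4.16-fold). On the lower side they were Nhsl1 (2.68-fold), Tbc1d24 (2.19-fold), Pdp1 (2.48-fold), Peli3 (3.35-fold) and Nudt11 (3.64-fold). DESeq2 called 982 higher and 513 lower genes, and edgeR without TAC replicate 2 called 2692 higher and 2785 lower. Without TAC replicate 3, edgeR called 2. The list calls of chemokines and cytokines, macrophage and monocyte markers, proliferation and the p53 response were also lost without it (adjusted p = 0.089 to 0.78). Epicardial, integrated stress and p53 calls were lost without TAC replicate 2 (0.066 to 0.074), the resting fibroblast call without TAC replicate 1 (0.14) and the p53 call without control replicate 2 (0.076).

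**Figure D3:**
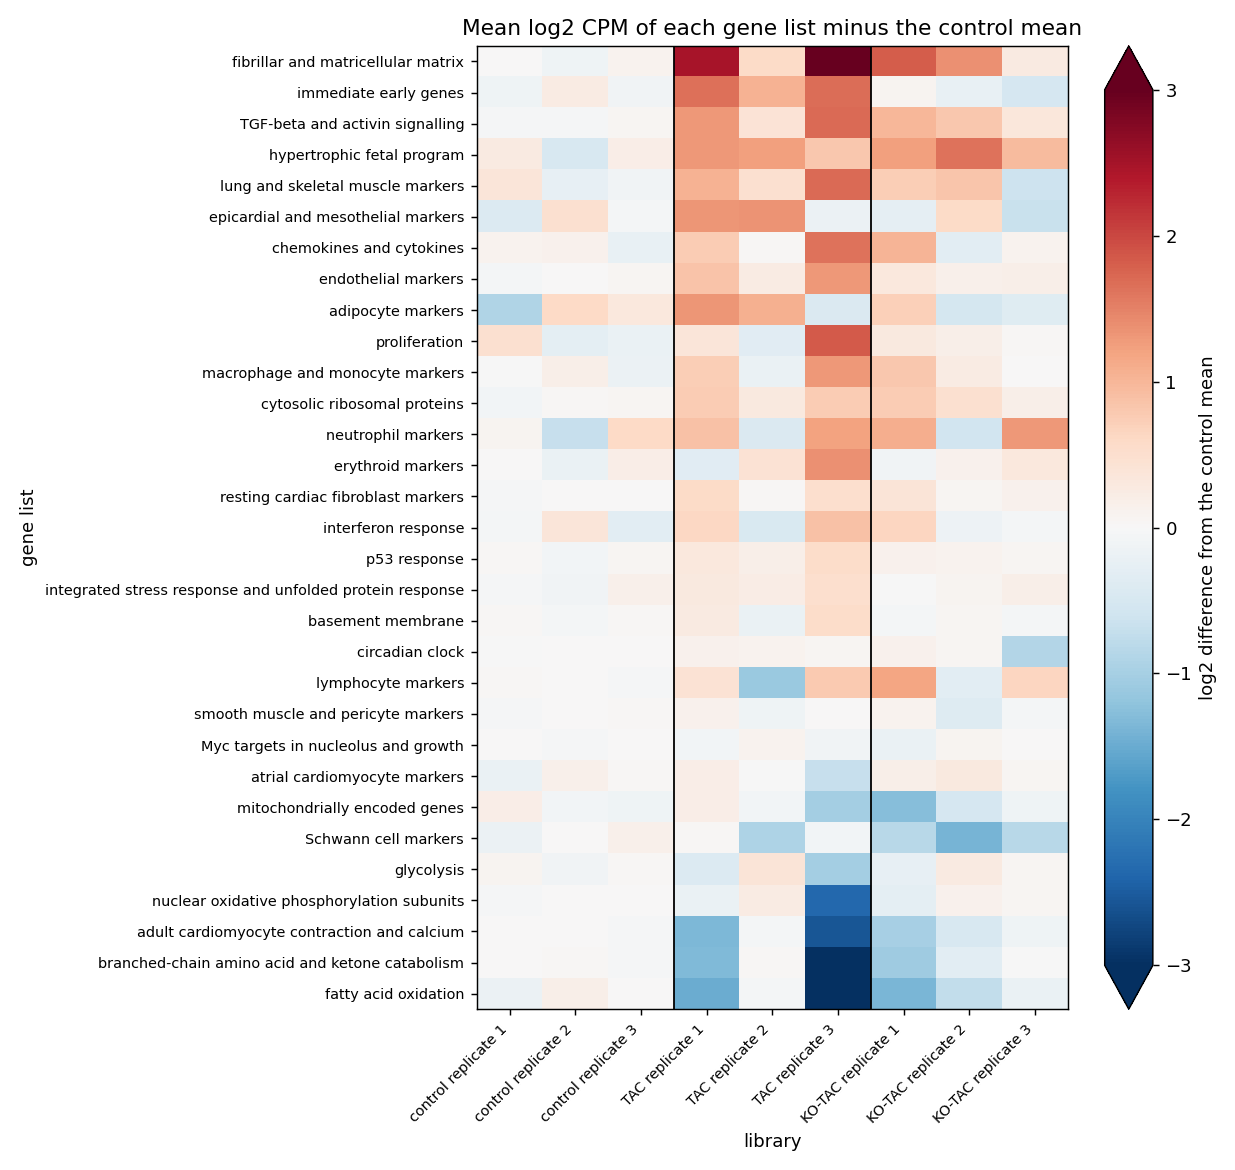
Mean log2 CPM of the members of each of the 31 gene lists (rows) in each heart (columns), as the difference from the mean of the control hearts, with red for higher and blue for lower and colours limited at 3. Immediate early genes are at 1.05 to 1.68 in the TAC hearts and -0.51 to 0.09 in the KO-TAC hearts, while the hypertrophic fetal program is at 0.8 to 1.31 and 0.96 to 1.64.

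Comparison of KO-TAC with TAC asked what the fibroblast deletion of Myc changed in loaded hearts. Immediate early genes fell as a list, with a median of -1.52 on the log2 scale and all 24 members lower, and this was the list call that held with an estimated correlation. Matrix genes fell as a list with a median of -1.12 and all 34 members lower (adjusted p = 0.54 with an estimated correlation), but with the endothelial minus cardiomyocyte level as a covariate the median was 0.15 and the call was lost (camera adjusted p = 0.63). Endothelial and epicardial markers fell with medians of -0.58 and -1.09, each with adjusted p = 0.50 with an estimated correlation. The hypertrophic fetal program was not called (median 0.23, camera adjusted p = 0.92 in the lower direction), and Nppa (783 ± 490 against 917 ± 460 CPM), Nppb (343 ± 69 against 321 ± 100 CPM) and Myh7 (3110 ± 1600 against 2610 ± 1200 CPM) differed by less than the spread between hearts. Oxidative phosphorylation, branched-chain amino acid catabolism, fatty acid oxidation and contraction genes were called as higher, with adjusted p of 0.63 to 0.66 with an estimated correlation, and those calls rested on TAC replicate 3.

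Of the immediate early genes, 23 of 24 passed when adjusted over the list alone. Atf3 was at 3.14 ± 0.72 CPM in KO-TAC against 21.8 ± 8.1 CPM in TAC hearts, and Nr4a1, an orphan nuclear receptor, at 7.55 ± 2.2 against 49.1 ± 28 CPM. Fosl2, a subunit of AP-1, was at 17.6 ± 2.8 against 50.5 ± 13 CPM and Btg2, an antiproliferative gene, at 26.3 ± 5.2 against 64.5 ± 9.7 CPM. For each of the 4 genes all 3 KO-TAC hearts lay below all 3 TAC hearts. Of all genes 9.96% separated, up or down, in this comparison, beside 10% by chance. The list's adjusted p was 8.1e-47 by camera, 0.0082 by fry and 0.013 with an estimated correlation. Against control hearts the KO-TAC median of the same list was -0.10 and was not called (camera adjusted p = 0.074). It was called as lower without control replicate 1 (0.01) or 3 (0.018), without KO-TAC replicate 1 (0.0015) or 2 (0.047), with no low-count filter (0.038) and with the covariate (median -0.30, 0.00047). With an estimated correlation it was not called by camera in the main fit (adjusted p = 0.94) or with the covariate (0.77). Hspa1a, an inducible heat-shock gene chosen after its values were seen, was 11.1-fold higher in TAC than in control hearts and 7.64-fold lower in KO-TAC than in TAC (6.94-fold and 4.8-fold without TAC replicate 2).

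Among matrix genes, Thbs1 (4.51-fold lower), Tnc (6.32-fold lower) and Ccn2 (2.41-fold lower) passed when adjusted over the list alone and 31 did not. Without TAC replicate 3 Tnc was 2.94-fold lower and Thbs1 alone passed, and without TAC replicate 2 31 members did. Thbs1 was also the 1 gene to pass without control replicate 1, 2 or 3 or without KO-TAC replicate 2 or 3, and Ccn2 did not pass without TAC replicate 1 or KO-TAC replicate 1. Postn was at 169 ± 120 against 510 ± 520 CPM and Col1a1 at 90.2 ± 24 against 177 ± 110 CPM, each with overlapping ranges, and Postn, 3.02-fold lower, was 1.34-fold lower without TAC replicate 3. The list had a camera adjusted p = 1.9e-12. Endothelial markers (camera adjusted p = 1.5e-08, 19 of 20 lower) included Rgcc, 2.45-fold lower, the 1 member that passed over the list alone (17 passed without TAC replicate 2, and 0 without control replicate 2, TAC replicate 1 or KO-TAC replicate 2 or 3). Epicardial and mesothelial markers (9.3e-05, 12 of 13 lower) included the epicardial transcription factor Wt1, 3.33-fold lower. Also called as lower were TGF-beta and activin signalling (median -0.47, camera adjusted p = 0.00044), proliferation (-0.95, 0.00079), chemokines and cytokines (-0.51, 0.00085), the integrated stress and unfolded protein response (-0.34, 0.0017), Schwann cell markers (-0.76, 0.005), and basement membrane (-0.22), macrophage and monocyte (-0.42), adipocyte (-0.63) and p53 response genes (-0.21), each of the last 4 at 0.013. Their adjusted p with an estimated correlation was 0.50 to 0.66. Cdkn1a was 3.77-fold lower, and the chemokine genes Ccl9 and Ccl6 were 3.03-fold and 2.38-fold lower, each passing over its list alone. Without KO-TAC replicate 2 none of these 3 passed, nor did Cdkn1a without KO-TAC replicate 1, or Wt1, Ccl9 and Ccl6 without KO-TAC replicate 3. Cxcl1 was at 0.937 ± 0.83 against 3.09 ± 1.3 CPM, 3.27-fold lower with overlapping ranges (edgeR adjusted p = 0.66; 6.63-fold without KO-TAC replicate 1), and Cxcr2 was at 0.0766 ± 0.071 CPM, with no difference detectable at this depth.

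The lists called as higher in KO-TAC were nuclear oxidative phosphorylation subunits (53 of 53 higher, median 0.35, camera adjusted p = 1.2e-05), branched-chain amino acid and ketone catabolism (0.54, 0.00025), fatty acid oxidation (0.50, 0.00073) and contraction and calcium genes (0.35, 0.0015), with 0 members passing over the list alone. Adjusted p was 0.63 to 0.66 with an estimated correlation, and with the covariate the first 3 lists were called as lower (medians -0.27, -0.25 and -0.38). Without TAC replicate 3 these 4 calls were lost, with medians of -0.09, 0.08, 0 and -0.01, and so were those of basement membrane, chemokines and cytokines, macrophages and monocytes, proliferation and the p53 response. Contraction, fatty acid oxidation and macrophage calls were also lost without KO-TAC replicate 3 (adjusted p = 0.05 to 0.15), the basement membrane call without KO-TAC replicate 1 (0.092) and the adipocyte call without TAC replicate 1 or 2 (0.095 and 0.14). Without TAC replicate 3 the immediate early genes (camera adjusted p = 8.1e-67) and the matrix genes (1.8e-05) were still called as lower, at medians of -1.27 and -0.37. With the covariate the calls of matrix genes (0.63) and of basement membrane, TGF-beta, chemokine, proliferation, Schwann cell and p53 genes (0.11 to 0.87) were lost, and macrophage markers were called as higher (median 0.30, 0.0091). Myc targets of the nucleolus and growth, a list fixed because Myc drives ribosome production, had a median of 0 with 28 members higher and 25 lower (camera adjusted p = 0.28). With the covariate 42 of its 53 members were lower and the list was called as lower, by a median of -0.10 (camera adjusted p = 0.0099, adjusted p = 0.60 with an estimated correlation). Immediate early genes were the list called with an estimated correlation in the fit with the covariate too (adjusted p = 0.044).

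Over all genes, edgeR called 0 in KO-TAC against TAC (lowest adjusted p = 0.13), with 1420 at an unadjusted p under 0.05 against 953 by chance, 859 of them lower. DESeq2 called 76 higher and 109 lower. The smallest p was again sought among genes whose groups did not overlap. On the lower side the smallest p belonged to Adamts1, a matrix-cleaving protease gene (27.7 ± 6.2 against 97.1 ± 5.7 CPM), Atf3, Sik1 (2.72-fold), Fosl2 and Arid5a (4.34-fold). On the higher side it belonged to Rpl3-ps2 (12.4-fold), Gadd45a (2.36-fold), Morn4 (3.60-fold), Rpl30-ps9 (6.61-fold, 10.1-fold without TAC replicate 1) and Cds1 (2.56-fold), as values that did not pass. Rpl3-ps2 and Rpl30-ps9 are pseudogenes that can share reads with the ribosomal protein genes they copy, and their values are uncertain. Without TAC replicate 2, edgeR called 2 genes higher and 11 lower. The lower ones included Atf3, Egr1, Egr2, Egr3, Nr4a1, Ier2, Junb, Adamts1, Sik1 and Thbs1.

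Comparison of KO-TAC with control asked how far loaded knockout hearts stood from control hearts, with genotype and operation combined. The hypertrophic fetal program rose as a list with a median fold of 2.41, 15 of 17 members higher (adjusted p = 0.08 with an estimated correlation). Cytosolic ribosomal protein genes (median fold 1.43, 49 of 50 higher), matrix genes (1.97, 32 of 34 higher) and TGF-beta and activin signalling genes (1.47, 19 of 20 higher) rose as lists, each with adjusted p = 0.94 with an estimated correlation. Fatty acid oxidation, contraction and calcium, mitochondrially encoded, branched-chain amino acid and Schwann cell genes fell, with medians of -0.61, -0.52, -0.42, -0.39 and -0.81 on the log2 scale. Their adjusted p with an estimated correlation was 0.94, and 0.49 for Schwann cell genes. Acta1, skeletal alpha-actin, was at 2470 ± 2200 against 112 ± 80 CPM, 22.0-fold higher and 11.3-fold without KO-TAC replicate 2. Nppa was 7.16-fold, Nppb 4.02-fold, Ankrd1 3.54-fold, Xirp2 2.41-fold and Gdf15 6.18-fold higher. Of the list 10 of 17 members passed when adjusted over the list alone, 3 without KO-TAC replicate 2 and 5 and 6 without control replicates 2 and 3.

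Camera gave the hypertrophic fetal program an adjusted p = 5.4e-13. Camera adjusted p was 1e-14 for ribosomal protein genes, 9.5e-11 for matrix genes, 2.6e-05 for TGF-beta and activin signalling, 2.9e-06 for fatty acid oxidation, 0.00043 for contraction and calcium genes and for mitochondrially encoded genes, 0.01 for branched-chain amino acid genes and 0.00095 for Schwann cell markers. With the covariate the calls of fatty acid oxidation (median 0.14, adjusted p = 0.95) and branched-chain amino acid genes (0.29, 0.099) were lost, and the matrix median was 0.23 in place of 0.98 (0.00066). That matrix call did not hold with an estimated correlation (camera adjusted p = 0.93). The Schwann cell call was lost with the filter of at least 1 CPM in 3 libraries (0.10) and the branched-chain call with limma-voom without weights (0.065). Without KO-TAC replicate 1 the calls of contraction and calcium, mitochondrially encoded and branched-chain amino acid genes were lost (adjusted p = 0.06 to 0.48). Postn was 5.61-fold, Ccn2 2.42-fold and Col1a1 1.23-fold higher, and Cxcl1 (0.937 ± 0.83 against 0.729 ± 0.29 CPM) and Cxcr2 overlapped between the groups.

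Over all genes, edgeR called 0 in KO-TAC against control (lowest adjusted p = 0.07), with 1098 at an unadjusted p under 0.05 against 953 by chance, and DESeq2 called 56 higher and 24 lower. Among genes whose groups did not overlap, the smallest p on the higher side belonged to the histone gene H2ac18 (5.93-fold), Arc (7.99-fold), Rpl3-ps2 (22.7-fold), Rpl3-ps1 (5.13-fold) and Psca. On the lower side it belonged to Tlcd4 (4.39-fold), Deptor (1.95-fold), Pcdhga5 (2.61-fold), Nhsl1 (2.17-fold) and Hspa12a (1.82-fold). Psca had 0 counts in the 3 control hearts and 13.2 ± 6.5 CPM in KO-TAC hearts, at least 998-fold higher against a floor of 3 counts over the group, which covers counting error only. Fitted to these 2 groups alone, without the TAC hearts in the estimate of the spread, edgeR called 16 genes higher and 14 lower.

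The TAC and KO-TAC comparisons were set against each other to see whether genes moved by TAC moved back in the knockout. With edgeR 0 genes passed both comparisons. At an unadjusted p under 0.05 in both, 1008 genes had opposite signs and 7 the same sign, against 200.3 opposite by simulation of unchanged groups that share the TAC libraries and 158.7 for independent lists. DESeq2 gave 131 opposite and 3 the same, against 4.4 opposite by the same simulation, run over 19051 genes, and 7.4 for independent lists among the 19701 genes tested in both. The simulation leaves out effects, draws genes independently and gives all groups 1 shared dispersion per gene. The TAC hearts in fact spread more (median SD of log2 CPM 0.604, against 0.171 in control and 0.33 in KO-TAC hearts). The simulated 200.3 and 4.4 may therefore be too low as chance values. The value for independent lists leaves out the shared libraries. Atf3, Hspa1a, Arid5a, Thbs1, Adamts1, Nr4a3, Egr3 and Cdkn1a were among the 131. The covariance of the log2 fold changes of TAC against control with those of KO-TAC against TAC was -0.494 (r = -0.72 across genes), beside -0.171 (r = -0.5) in the simulation and -0.314 from the observed spread of the TAC hearts, a difference of -0.18 from the latter. Part of the excess may come from the shared TAC libraries, which are too few to be split. For TAC and KO-TAC each against control the covariance was 0.407 (r = 0.65), beside 0.172 (r = 0.5) in the simulation and 0.098 from the observed spread of the control hearts.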

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

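DESeq2 without TAC replicate 2 or 3, the robust fit, limma-voom without weights, summed rows, removal of nuclear mitochondrial copies and the cell-type covariate were chosen after seeing the data. The edgeR counts of 0 genes held in each comparison with RLE and upper-quartile factors, library size alone, the 1 CPM filter, mitochondrial genes removed, the fold threshold of 1.2 and the added edgeR fits and limma-voom without weights, and changed with the tool. DESeq2 called 1495 genes in TAC against control, 185 in KO-TAC against TAC and 80 in KO-TAC against control, and limma-voom with quality weights 7230, 996 and 991, having given TAC replicates 2 and 3 weights of 0.204 and 0.156. Of the DESeq2 calls, 1471, 179 and 79 had an unadjusted edgeR p under 0.05. In KO-TAC against control 2 genes passed with no low-count filter (Arc and H2ac18) and 30 in a fit of only the 2 groups compared. With each library left out edgeR called 0 to 5477 genes in TAC against control (5477 without TAC replicate 2, 2 without TAC replicate 3, 1 without TAC replicate 1). They were 0 to 13 in KO-TAC against TAC (13 without TAC replicate 2, 1 each without TAC replicate 3, control replicate 2 or KO-TAC replicate 3) and 0 to 4 in KO-TAC against control (3 without TAC replicate 2, 4 without TAC replicate 3). DESeq2 called 6946, 3490 and 342 without TAC replicate 2, and 621, 133 and 273 without TAC replicate 3. Genes that passed in opposite directions numbered 131 with DESeq2, 935 with quality weights, 0 to 13 with a library left out (13 without TAC replicate 2, 1 without TAC replicate 3), and with DESeq2 3196 without TAC replicate 2 and 82 without TAC replicate 3. Myc in KO-TAC against TAC stayed negative under every alternative run (-1.74 to -1.06) and passed with quality weights (-1.74, adjusted p = 0.031) and with DESeq2 without TAC replicate 2 (-1.71, adjusted p = 0.0019), the adjusted p ranging from 0.0019 to 0.98. Fewer libraries or another model of the spread enter these fits; the cause was not tested further.

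Lists called were 17, 17 and 9 in the 3 comparisons in the order above. With an estimated correlation they were 0, 1 and 0, so that all of them but that of immediate early genes in KO-TAC against TAC rest on the preset correlation. Fry, which tests a list against no change, called 2, 1 and 0. With a library left out they were 13 to 18, 11 to 23 (11 without TAC replicate 3) and 7 to 14 (14 without KO-TAC replicate 2), and 12 to 17, 8 to 17 and 6 to 9 of the original calls were kept in direction. Library size alone moved the median log2 difference of all genes to 0.29 in TAC and 0.28 in KO-TAC against control, and turned the direction of 0 called lists. Other settings ended some of these calls: for p53 in TAC against control library size alone, both limma-voom fits and the 1 CPM filter (adjusted p = 0.068 to 0.37), and there quality weights also for nuclear oxidative phosphorylation (0.091) and integrated stress (0.13). In KO-TAC against TAC they were quality weights for proliferation (0.096) and p53 (0.3), the 1 CPM filter for adipocyte markers (0.084) and p53 (0.058) and limma-voom without weights for adipocyte markers (0.055). In KO-TAC against control they were the 1 CPM filter for Schwann cell markers (0.1) and limma-voom without weights for branched-chain genes (0.065). With the endothelial minus cardiomyocyte level as a covariate, 7 of 15, 4 of 15 and 6 of 8 called lists, leaving out the endothelial and contraction lists that make it, kept call and direction, and 5, 4 and 0 were called the opposite way by camera. Another 5 lists in each comparison were called with the covariate and not in the fit without it, and with an estimated correlation too 0, 1 and 0 of 29 lists were called. Among lists called with or without it, medians that turned were those of fatty acid oxidation (0.48), oxidative phosphorylation (0.73), branched-chain (0.41), chemokine (-0.15), macrophage (-0.23) and proliferation genes (-0.49) in TAC against control, and among lists not called without it glycolysis (0.45), mitochondrially encoded (0.41), lymphocyte (-1.19) and interferon genes (-0.47). In KO-TAC against TAC they were those of the same lists (-0.38, -0.27, -0.25, 0.41, 0.3 and 0.24), matrix (0.15) and TGF-beta genes (0.06), glycolysis (-0.17), interferon genes (0.36) and Myc targets (-0.1, from 0), and in KO-TAC against control those of fatty acid oxidation (0.14), branched-chain (0.29) and proliferation genes (-0.21). Of the lists called in neither fit, 3, 4 and 7 medians also turned, 1 of the 7 from 0. The replicate number as a block gave 0 genes in each comparison and 17, 19 and 10 lists, and Myc in KO-TAC against TAC at -1.45 in the blocked fit. The numbers, taken from the titles, do not pair the hearts: same-numbered hearts had correlated deviations of 0.007, 0.037 and 0.001 (control with TAC), -0.007, -0.029 and 0.018 (control with KO-TAC) and 0.106, 0.124 and -0.255 (TAC with KO-TAC). The sample descriptions number the TAC hearts 2 to 4 instead. By those numbers 2 hearts per pair of groups share a number, with correlations of -0.007 and -0.001 (control with TAC) and -0.008 and 0.327 (TAC with KO-TAC), which do not show a pairing either.

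Directions turned for genes whose groups lay close together, none of which had passed. Cxcl1 in KO-TAC against control was -0.26 with quality weights and -0.65 to 0.78 with a library left out (-0.65 without KO-TAC replicate 1). Cxcr2 in KO-TAC against TAC was -0.03 with library size alone, -2.12 with quality weights, -0.58 to 0.67 with a library left out (-0.58 without KO-TAC replicate 3, -0.43 without TAC replicate 2), and -0.48 with DESeq2 without TAC replicate 2, and in TAC against control 0.05 with quality weights. In KO-TAC against TAC Myh7 was -0.05 with quality weights and -0.2 to 0.7 with a library left out (-0.2 without KO-TAC replicate 2). Nppa was -0.8 to 0.15 with a library left out (0.06 without TAC replicate 1, 0.15 without KO-TAC replicate 3). Nppb was -0.14 to 0.25 with a library left out (-0.14 without TAC replicate 3, -0.04 without KO-TAC replicate 2) and -0.13 with DESeq2 without TAC replicate 3. Tcf21 in TAC against control was -0.03 to 0.16 with a library left out (-0.03 without control replicate 1). The cause was not tested. For the other named genes 50 values with a library left out and 307 under other settings passed where the edgeR fit had not. Depth limits Cxcr2, at most 0.151 CPM in a group mean.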

Other observations

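The length test, the fit with a cell-type covariate for KO-TAC against TAC and the splits of the samples were chosen before their results were seen; the same fit for TAC against control and the tests on single TAC libraries, heat-shock genes, the Myc locus, shared reads, the hypertrophic genes of TAC replicate 2 and cell-type gaps were chosen after.

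Lists not called also describe the hearts. In TAC against control, basement membrane (camera adjusted p = 0.25), mitochondrially encoded genes (0.33), glycolysis (0.47), Myc targets (0.84), neutrophil (0.11), lymphocyte (0.84), smooth muscle and pericyte (0.84), adipocyte (0.15), Schwann cell (0.84), atrial (0.84), lung and skeletal muscle (0.14) and erythroid markers (0.14), the interferon response (0.05) and the circadian clock (0.84) did not pass. In KO-TAC against TAC, resting fibroblast markers (0.055), mitochondrially encoded genes (0.064), glycolysis (0.14), ribosomal proteins (0.055), neutrophil (0.54), lymphocyte (0.14), smooth muscle and pericyte (0.17), atrial (0.52), lung and skeletal muscle (0.09) and erythroid markers (0.055), the interferon response (0.055) and the circadian clock (0.25) did not pass. In KO-TAC against control the 22 lists not called had camera adjusted p of 0.074 to 0.83. With the endothelial minus cardiomyocyte level as a covariate, 5 of these lists were called in each comparison. In TAC against control glycolysis (median 0.45, camera adjusted p = 1.3e-06), mitochondrially encoded genes (0.41, 0.033) and Myc targets (0.20, 0.028) were then higher and lymphocyte markers (-1.19, 0.0011) and the interferon response (-0.47, 3e-04) lower. In KO-TAC against TAC mitochondrially encoded genes (-0.61, 4.2e-07), glycolysis (-0.17, 0.028) and Myc targets (-0.10, 0.0099) were lower and lymphocyte markers (1.47, 2.6e-05) and the interferon response (0.36, 0.0098) higher. In KO-TAC against control oxidative phosphorylation (0.48, 2e-11) and glycolysis (0.40, 0.00017) were higher and basement membrane (-0.16, 0.0095), proliferation (-0.21, 0.024) and immediate early genes (-0.30, 0.00047) lower. None of these 15 calls held with an estimated correlation (adjusted p = 0.31 to 0.93). Schwann cell markers were 0.83 to 1.39 below the control mean on the log2 scale in the 3 KO-TAC hearts, and 0.92 below it in TAC replicate 2. KO-TAC replicate 3 had circadian clock genes at -0.87, while the other 5 operated hearts were at 0.06 to 0.13. The ratio of mt-Nd5 to mt-Co3 counts, both from the mitochondrial genome, was 1.548 to 1.632 in control, 0.8087 to 1.187 in TAC and 0.1731 to 1.059 in KO-TAC hearts. Il6 had 0 counts in control hearts and 0.983 ± 1.3 CPM in TAC hearts (SD, n = 3), at least 74.2-fold higher against a floor of 3 counts over the group, but 0.248 CPM and at least 18.7-fold higher without TAC replicate 3. Il6 was chosen after its values were seen.

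Immediate early genes were higher in TAC hearts than in control and KO-TAC hearts. A single TAC library is argued against, since the list mean was 1.05 to 1.68 above control in the TAC hearts and -0.51 to 0.09 in the KO-TAC hearts. The list was also called in KO-TAC against TAC without each TAC library, with a highest camera adjusted p of 3.2e-33. Those fits used the preset correlation, and the estimated one was not run with a library left out. A larger share of RNA from endothelial cells relative to cardiomyocytes is argued against as the whole cause of the gap between KO-TAC and TAC. With the endothelial minus cardiomyocyte level of each heart as a covariate the median was -1.25 (SD 0.78 across members), against -1.52 without it. Of the members 24 of 24 were still lower, whereas the matrix median went from -1.12 to 0.15 (camera adjusted p = 0.63). This level does not follow fibroblasts, immune or epicardial cells by themselves, and contraction genes can change within cardiomyocytes, so other shares stay open. TAC replicates 1 and 3 (1.25 and 2.91) lay above every KO-TAC heart (-0.64 to 0.35), so the adjusted gap leans on TAC replicate 2 and on extrapolation. For the gap between TAC and control a larger share of RNA from cells other than cardiomyocytes cannot be told apart from a change within cells. There the median fold went from 2.67 to 1.63 (0.70 on the log2 scale, SD 0.94 across members, camera adjusted p = 4.9e-18) and the matrix median from 2.36 to 0.29. Handling at tissue collection cannot be told apart from an effect of Myc deletion, tamoxifen or Cre, because no label records the collection and 9 of 12 heat-shock genes were lower too (median -0.41), led by Hspa1a and Hspa1b; a lower stress response in knockout hearts is a hypothesis that stays open beside it.

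Psca and Arc were higher and Lypd2 lower in KO-TAC hearts, and the 3 genes lie together on chromosome 15 (Arc from 74669083 to 74672570, Psca from 74714839 to 74717069, Lypd2 from 74732247 to 74734329), 12.7 Mb from Myc. Psca was at 5.85 to 17.9 CPM in KO-TAC hearts and at most 0.405 CPM elsewhere, Arc at 14.7 to 28.7 CPM against at most 8.21 CPM, and Lypd2 had 0 counts in the KO-TAC hearts, at least 65-fold below control (0.684 CPM) but at least 11.4-fold below TAC hearts, where it was already at 0.0532 to 0.156 CPM. Reads passing from Lypd2 to Psca are argued against, since Psca in KO-TAC hearts was 19.3 times the level Lypd2 had in control hearts. Alleles carried along with the floxed Myc locus are a candidate explanation that cannot be told apart from an effect of the deletion: with these genes, Myc and Deptor left out, the share of genes with p under 0.01 within 20 Mb of Myc was at the 33.3 percentile of windows elsewhere (96.6 with them in). The test first counted those genes and took a share below the median window as evidence against this explanation. Both were changed after the values were seen, the bound because a few linked alleles need not raise the share. Taken on the percentile (33.3), the earlier bound would have argued against this explanation. Taken on the share it would not, since the share (0.338%) equalled that of the median window (0.338%). Floxed hearts without Cre or the mice's background genotype are needed to decide.

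TAC hearts differed from one another more than control or KO-TAC hearts did. A control heart under a wrong label as TAC replicate 2 is argued against, since 14 of the 17 hypertrophic genes lay above the highest control there. A lower share of cardiomyocytes alone is argued against, because in TAC replicates 1 and 3 the matrix median exceeded that of smooth muscle and pericyte markers by at least 1.9 on the log2 scale, and in TAC replicate 3 cardiomyocyte genes differed from the control mean unequally (Atp2a2 -4.83, Tnnt2 -1.21, Myh7 0.73). RNA length bias as the source of the distance of TAC replicate 3 from control hearts is argued against by a correlation of -0.02 between transcript length and its difference from control, across genes. The other 5 operated hearts were at -0.23 to -0.16 and control hearts at -0.07 to 0.08, so a length shift in those 5 stays open. A length difference between TAC replicate 3 and TAC replicates 1 and 2 (-0.18 and -0.17) stays open too, since the test compared it with control hearts only. Different severity of the load among the mice is a hypothesis that no label here can test.

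With 3 hearts against 3, the 10 splits of the samples are too few for a share under 0.05. For lists the real grouping called 17 in TAC against control and the highest other split 18 (3 splits gave as many), 17 and 19 in KO-TAC against TAC (4 splits), and 9 and 14 in KO-TAC against control (9 splits). For genes the real count was 0 in each comparison, so 10 of 10 splits had to give as many and that share says nothing. The highest other split gave 1 gene in TAC against control, 0 in KO-TAC against control and 3091 in KO-TAC against TAC. This last one set KO-TAC replicate 1 with TAC replicates 1 and 3, which points to a structure of the samples across the groups. Those 3 hearts had endothelial minus cardiomyocyte levels of 0.35 to 2.91, against -0.67 to -0.32 in the hearts set against them. At an unadjusted p under 0.05 the real grouping gave 4054 genes in TAC against control and the highest other split 2262. In KO-TAC against control these were 1098 and 337. In KO-TAC against TAC the real grouping gave 1420, and other splits gave 1423 and 6758. Genes that passed both TAC comparisons with opposite signs numbered 0 in the real grouping, so 100 of 100 relabellings of the 9 hearts had to give as many, and the highest gave 2473; nothing about chance follows from it.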
